A study of Homo sapiens with 6 samples.

How the data were processed

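RNA was sequenced from A2780 cells, an established human ovarian cancer line that the labels describe as serous, after transfection with an siRNA against FOXM1 (si-FOXM1, 3 libraries) or with the siRNA labelled si-NC (3 libraries). The deposited table marks the si-NC columns as control. Total RNA was taken up in Trizol and made into Illumina libraries, per the labels' protocols. The table's column names read B2780 where the labels read A2780, and columns were matched to samples by transfection and replicate number. The design text speaks of triplicates that were biological and experimental without saying which libraries were which. The p-values therefore measure the spread between these libraries, which may be technical.

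The authors deposited 1 table of 12174 genes. It holds an expected count per gene and library, which is an estimated read count that need not be whole. It also holds FPKM per gene and library, per the file headers. The authors' own log2 fold changes, p-values and adjusted p-values stand beside them in the deposited table. TopHat, Cufflinks and the hg19 build are named without versions or roles, per the submitters' processing notes. The tool that counted reads, the annotation, the use of strand and the authors' scaling are not given in the sources used here. Of the deposited expected counts, 14.5% to 17.9% per library were not whole numbers. Every one of the 12174 genes exceeded 1 CPM in at least 3 libraries, so genes below that level were not analysed here.

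Expected counts were rounded to whole numbers and fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, all 6 libraries, the group as the only term and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, and a positive log2 fold change means higher in si-FOXM1. The edgeR filter filterByExpr, with its defaults, removed 0 genes. Levels are TMM-normalised CPM (counts scaled to the library total times its TMM factor), given as mean ± SD over 3 libraries. The library totals, from 14972972 to 18809099 counts, set the counting precision of these levels. TMM factors were 0.914 to 0.916 in si-NC and 1.08 to 1.1 in si-FOXM1.

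Before the data were examined, 28 gene lists, the tests, most of the other settings and the rule for named genes were fixed. The rule took FOXM1, then the 10 largest falls and 10 largest rises with an adjusted p under 0.05, a mean of at least 1 CPM in both groups, no overlap between the libraries of the groups and a gene symbol, then up to 4 members of each list with the smallest p. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The rotation test fry was run beside them; it asks whether a list's genes moved on balance in 1 direction and does not compare them with other genes. List p-values were adjusted over the 24 lists tested.

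Transcript GC content, length, exon overlaps and untranslated regions came from GENCODE release 29 on GRCh38, taken by gene symbol, with the gene's transcript of longest coding sequence. That build differs from the authors' hg19, so no coordinates are given. A GC value was found for 11708 genes (96.2%), 485 of them through an older symbol, and an annotated 3' UTR for 11271. Exons of 6001 genes overlapped those of another gene.

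A trend of fold change with GC content was seen after the fit, and a GC-corrected fit was then added. In each library, the deviation of a gene's log2 CPM (prior count 1) from its mean was fitted on GC content with a natural spline of 6 degrees of freedom, and the fitted curve entered edgeR as an offset. A further fit added a spline of log2 transcript length with 4 degrees of freedom. These corrections assume that GC content itself had no part in the response, and they remove any real change that follows it.

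Words of 6, 7 and 8 bases in the 3' UTR were also scanned after the fit, on 9718 genes with a mean of at least 4 CPM and a 3' UTR of at least 50 bases, FOXM1 left out. The fold change was first regressed on splines of GC content, level and region lengths and on base-pair composition, residuals were limited to ±2, and each word present in at least 40 genes was tested. The spread expected by chance came from 100 permutations of the residuals over genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 were used. The siRNA sequences were not given in the sources used here.

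The procedures were tested on simulated data. Counts drawn for the 12174 genes of the si-FOXM1 and si-NC comparison, with 200 genes changed, gave correct calls for 37 of 50 genes at 1.25-fold, 41 of 50 at 1.5-fold, 49 of 50 at 2-fold and 50 of 50 at 4-fold, and 7 of 11974 unchanged genes were called. When a linear GC trend was added to 11708 simulated genes, 75.9% of the unchanged genes were called without the correction and 0.04% with it. In the real data 79.5% of genes were called and the trend flattened at high GC content. The simulation, with 200 genes changed, therefore does not show how well the correction works there. With the correction, the calls were correct for 24 of 50 genes at 1.25-fold, 36 of 50 at 1.5-fold, 45 of 50 at 2-fold and 50 of 50 at 4-fold. In 25 simulated lists of 25 genes, over 12174 genes, the 1 shifted list was called and 0 of the others. These lists held random genes drawn independently, so they cannot show how often camera calls lists of correlated genes. In the real lists the estimated inter-gene correlation reached 0.897, for cytosolic ribosomal proteins. In the word scan of 9718 genes, 5 of 5 words planted at -0.12 log2 ranked first.

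Other settings chosen before the data were examined were no filter, at least 50 counts in at least 3 libraries, DESeq2 1.42.0 size factors, library size alone, the replicate number as a block, the DESeq2 Wald test, limma on log2(FPKM + 0.1) for genes at 1 FPKM or more in at least 3 libraries, leaving out each library in turn, a minimum fold of 2, and the authors' adjusted p in place of their p-value. Settings added after seeing the data were the GC corrections, the same without genes that carry the word AGATAT, limma on log2(FPKM + 1), the forkhead list without FOXRED1, and the uncorrected fit on genes with a GC value.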

Results

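The series asked how the transcriptome of A2780 ovarian cancer cells changed when FOXM1 was knocked down. FOXM1 is a forkhead transcription factor known to drive genes of the G2 and M phases of the cell cycle. Gene expression was measured by RNA sequencing in 3 libraries of si-NC cells and 3 of si-FOXM1 cells. The libraries held between 14972972 and 18809099 counts over 12174 genes. Log2 CPM correlated at 0.991 to 0.9938 across genes within a group and at 0.9373 to 0.9465 between groups. Every pair of libraries of a group differed by more than sampling noise, with a mean chi-square of 2.24 to 6.8 per gene.

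FOXM1 itself was measured first in every library. It stood at 200.3, 208.6 and 211.7 CPM in the si-NC libraries and at 16.88, 16.18 and 14.2 CPM in the si-FOXM1 libraries. The mean fell from 207 ± 5.89 to 15.8 ± 1.39 CPM (SD, n = 3 each; edgeR adjusted p = 1.66e-17), a log2 fold change of -3.72 (SE 0.06; GC-corrected -3.44) that left 7.61% of the si-NC level. The exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest p this design allows. Exons of FOXM1 overlap those of another gene, and the authors' use of strand in counting is not given in the sources used here.

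**Figure D1:**
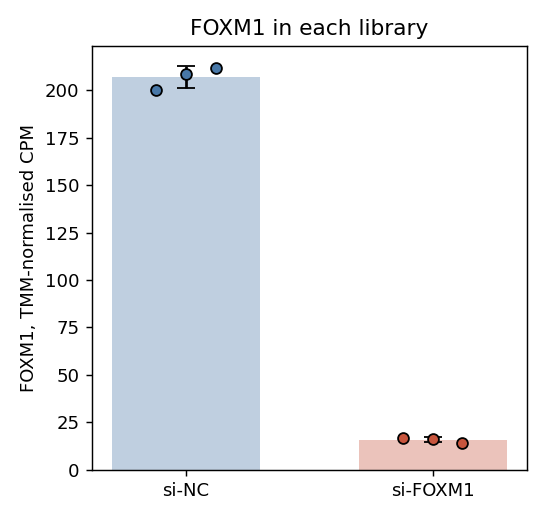
FOXM1 in TMM-normalised CPM in each library; bars are group means, error bars the SD and points the 3 libraries of each group. The si-NC libraries lie between 200.3 and 211.7 CPM and the si-FOXM1 libraries between 14.2 and 16.88 CPM.

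Most measured genes differed between the groups. Of 12174 genes, 4922 were called higher and 4762 lower in si-FOXM1, and 1749 of the higher and 415 of the lower genes changed at least 2-fold. Libraries of the groups did not overlap for 80.1% of genes, where chance gives 10%. The split of calls depended on scaling: library size alone gave 6266 higher and 3220 lower, with the median gene shifted by 0.26 on the log2 scale. A fit that also differed in measure, test and genes, limma on log2(FPKM + 1) over 11355 genes, gave 5404 higher and 3092 lower, with a shift of 0.17. The directions given below are relative to the TMM scaling. The authors' deposited p-value was under 0.05 for 9870 genes, among them all 9684 called here. Their adjusted p-value was under 0.05 for 9778 genes, 9682 of which were also called here, all 9682 in the same direction.

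Fold changes followed the GC content of the transcripts. The median log2 fold change went from 1.00 in the tenth of genes with the lowest GC content (31.2% to 39%) to -0.55 in the tenth with the highest (62.7% to 79.8%). Across 11708 genes, which are not independent replicates, Spearman's rho was -0.71. After correction for this trend 7726 genes were called, 3339 higher and 4387 lower, and 813 of them changed at least 2-fold. Of the genes called before and after correction, 5388 kept their direction and 1100 took the opposite one, while 2900 were called only before and 1238 only after. GC-corrected values are therefore given for the genes and lists below.

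**Figure D2:**
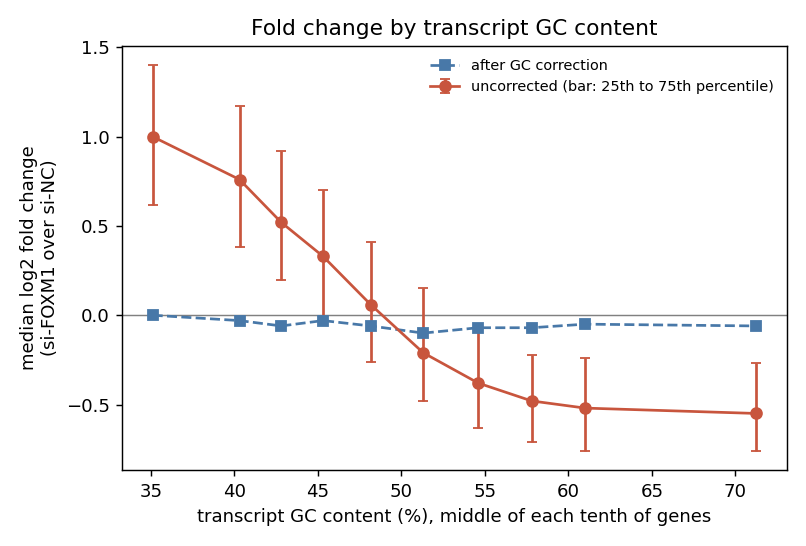
Median log2 fold change (si-FOXM1 over si-NC) of genes in 10 equal groups by transcript GC content in percent; circles are uncorrected values with bars from the 25th to the 75th percentile, squares the GC-corrected medians. The uncorrected median goes from 1.00 to -0.55, and the corrected medians lie between -0.1 and 0.

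The largest falls after FOXM1 itself were led by UNG, the uracil-DNA glycosylase that removes uracil from DNA. UNG went from 105 ± 2.11 to 15.1 ± 0.29 CPM (SD, n = 3 each), a log2 fold change of -2.80 (SE 0.06, edgeR adjusted p = 3.17e-16; GC-corrected -2.72). USP18, a protease that removes ISG15 and restrains interferon signalling, fell by 2.01 on the log2 scale (SE 0.08; GC-corrected -1.87). SLC2A1, the glucose transporter GLUT1, went from 243 ± 3.76 to 65.6 ± 0.92 CPM (log2 -1.89, SE 0.04; GC-corrected -1.57). CDCA4 fell from 156 ± 1.71 to 43.9 ± 2.37 CPM (log2 -1.83, GC-corrected -1.65), CCR1, a chemokine receptor, from 66.1 ± 2.46 to 19.6 ± 1.65 CPM (log2 -1.75, GC-corrected -2.03), and SCML2, a Polycomb-group protein, from 43.9 ± 1.24 to 13.1 ± 0.85 CPM (log2 -1.75, GC-corrected -2.56). The other falls named by the rule were RTN4R (log2 -1.95), IGDCC3 (-1.86), the secreted ligand gene WNT5B (-1.79) and the mitochondrial MT-ND5 (-1.72), with edgeR adjusted p between 4.01e-14 for MT-ND5 and 6.87e-06 for WNT5B. Their GC-corrected values were -1.46, -1.40, -1.36 and -2.10. RTN4R, IGDCC3 and WNT5B were at low levels, with means of 10.1, 11.5 and 5.19 CPM in si-NC and 2.62, 3.17 and 1.49 CPM in si-FOXM1. All 10 were also called lower after GC correction. Of the 9 with an annotated 3' UTR, UNG, SLC2A1, CDCA4, SCML2 and RTN4R carried the word AGATAT there. Among the 10 largest rises 9 could be searched and 3 carried it. The share was 26.4% among genes not called at least 2-fold lower after GC correction. These counts are not adjusted for 3' UTR length. Across all genes scanned, genes with this word were lower relative to other genes after regression on base composition, level and lengths (effect -0.11 log2, SE 0.012, 2690 genes). Among the genes named below it was also in ZNF195, ANKRD12, ZNF107, MDM2, GADD45A, BRIP1, IFIT1, ZEB1, SOD2, LSS, ZNRF3, TFDP1, AGO2, AGO3, LUM, DCN, SGPP1, TMEM64, UHMK1 and SHISA9.

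The largest rises were in genes of low level in si-NC. WBP4, a spliceosome-associated protein, rose from 2.94 ± 0.21 to 26.1 ± 3.22 CPM (log2 3.14, SE 0.13; edgeR adjusted p = 6.89e-13; GC-corrected 2.30), and NEXN, an actin-binding protein, from 2.01 ± 0.29 to 15.7 ± 0.84 CPM (log2 2.98; GC-corrected 2.08). MPHOSPH10, a component of the small-subunit processome, rose from 6.31 ± 0.22 to 36.9 ± 1.24 CPM (log2 2.54; GC-corrected 1.82). The zinc finger genes ZNF195 (log2 2.87), ZNF765 (2.72), ZNF107 (2.64) and ZNF83 (2.56) were among the 10, with GC-corrected values of 2.22, 1.86, 1.504 and 1.88. TIAF1 (log2 2.77), ANKRD12 (2.68) and the antisense RNA CERS6-AS1 (2.55) completed them, with GC-corrected values of 2.97, 1.58 and 1.72. The rises of WBP4, NEXN, TIAF1, ZNF765, ANKRD12, ZNF107 and CERS6-AS1 are uncertain because their exons overlap those of other genes, and zinc finger genes can share reads with near-identical relatives. CDCA4 and SLC2A1 overlapped other genes as well, as did PLK1, CCNF, MCM2, MCM7, MDM2, LIG1, SREBF2, LSS, ENO1, ALDOA, HSP90B1, ZEB1, ITGB1, SOD2, IRF1, IFITM3, KRT8, KRT18, KRT10, AXL, CTSD, RBL2, FOXK2, FOXRED1, AGO2, AGO3, TARBP2, JUNB, RPL8, RPS2, RPL13, GAPDH, COL3A1 and CD68 among the list genes named below.

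The 50 genes of the FOXM1 and G2/M list, which hold textbook FOXM1 targets, moved in both directions. Of these, 23 rose and 23 fell, and the counts adjusted over the list alone were the same. The cyclin F gene CCNF fell from 141 ± 6.24 to 48.7 ± 1.38 CPM (log2 -1.54, GC-corrected -1.12), CDC25B, a phosphatase that activates CDK1, from 109 ± 4.54 to 38.1 ± 0.59 CPM (log2 -1.51, GC-corrected -1.06), and the mitotic kinase PLK1 from 421 ± 5.04 to 176 ± 5.05 CPM (log2 -1.26, GC-corrected -0.86). CENPF, a kinetochore protein, rose from 35.6 ± 3.42 to 128 ± 10.9 CPM (log2 1.84; GC-corrected 1.08). The list did not stand apart from other genes (camera adjusted p = 0.98; 0.99 with an estimated correlation), and its median of 0.05 and mean of 0.10 were above 0 while camera's direction was down. Its mean GC content was 45.8%, and within it fold change fell by 1.16 log2 per 10 GC points (SE 0.10). After GC correction 12 rose and 28 fell (13 and 28 adjusted over the list alone) with a median of -0.20 (camera adjusted p = 0.10, 0.46 with an estimated correlation). With transcript length corrected too, camera's adjusted p was 0.046, and among genes without AGATAT in the 3' UTR the GC-corrected value was 0.016, both downward; over all settings the adjusted p of the list ran from 0.0163 to 0.988.

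Of the 38 measured G1/S and E2F targets, 13 rose and 22 fell, the same as adjusted over the list alone. MCM2 and MCM7, subunits of the replicative helicase, fell by 1.20 and by 0.78 on the log2 scale, and the thymidine kinase gene TK1 fell by 0.95. After GC correction MCM2, MCM7 and TK1 stood at -0.77, -0.35 and -0.46. The list was not called by camera (adjusted p = 0.14; 0.56 with an estimated correlation) but was lower by fry. After GC correction 5 rose and 26 fell, adjusted over all genes and over the list alone, and the list was called lower (camera adjusted p = 0.0084; 0.46 with an estimated correlation). It was also called lower with the DESeq2 Wald test (0.00973), and over all settings its adjusted p ran from 0.00518 to 0.327. Among the 15 genes of the DREAM, MuvB and B-MYB list, 6 rose and 5 fell, the same as adjusted over the list alone (camera adjusted p = 0.92). TFDP1, a dimer partner of E2F factors, fell by 1.31 on the log2 scale, and MYBL2, which encodes B-MYB, fell by 1.08. E2F4 fell by 0.71 and RBL2 rose (log2 0.94). The GC-corrected values were -1.54 for TFDP1, -0.62 for MYBL2, -0.29 for E2F4 and 0.39 for RBL2. After GC correction 3 rose and 8 fell in this list, 4 and 8 adjusted over the list alone (camera adjusted p = 0.46).

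Of 31 measured p53 targets and CDK inhibitors, 18 rose and 7 fell, the same as adjusted over the list alone, with a median log2 fold change of 0.26. MDM2, which encodes the ubiquitin ligase of p53, rose from 81.9 ± 1.86 to 192 ± 7.05 CPM (log2 1.23; GC-corrected 0.57). RRM2B (log2 1.39), GADD45A (1.08) and BTG2 (0.76) also rose, with GC-corrected values of 0.83, 1.21 and 0.82. The list was not called by camera before correction (adjusted p = 0.14; 0.37 with an estimated correlation). It was called higher by fry, and by camera with library size alone (0.0483), the DESeq2 Wald test (0.0457) and limma on FPKM at a pseudocount of 0.1 (0.0498), and over all settings its adjusted p ran from 0.000358 to 0.166. After GC correction 19 rose and 6 fell and it was called higher (camera adjusted p = 0.0033; 0.14 with an estimated correlation).

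Before correction DNA repair was the only list called higher by camera at the preset correlation in the edgeR fit with TMM, while fry called it, p53 targets, redox defence and fibroblast markers higher. Of its 35 measured members 23 rose and 8 fell (23 and 9 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.039; 0.37 with an estimated correlation). BRIP1, a helicase that partners BRCA1, rose from 14.6 ± 1.27 to 39.8 ± 1.39 CPM (log2 1.44; GC-corrected 0.45). The histone gene H2AFX fell by 0.80 and the ligase gene LIG1 fell by 0.86 (GC-corrected -0.31 and -0.39). The mean GC content of the list was 44.7%, against 50.4% over all genes. After GC correction 13 rose, 11 fell and the median was 0.01 (camera adjusted p = 0.61), and without si-FOXM1 replicate 3 the uncorrected adjusted p of the DNA repair list was 0.057. With limma on log2 FPKM it was 0.0776 at a pseudocount of 0.1 and 0.0834 at a pseudocount of 1, and over all settings it ran from 0.0255 to 0.725.

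Genes of glycolysis and hypoxia fell. Of 25 measured, 22 fell and 1 rose, the same as adjusted over the list alone, with a median of -0.69 (camera adjusted p = 2.05e-05; 0.29 with an estimated correlation). Beside SLC2A1, the pyruvate kinase gene PKM fell from 3444 ± 39.6 to 1713 ± 29.4 CPM (log2 -1.01), the enolase gene ENO1 from 4534 ± 42.2 to 2414 ± 50.6 CPM (log2 -0.91) and the aldolase gene ALDOA from 3115 ± 21.5 to 1828 ± 55.9 CPM (log2 -0.77). The list was richer in GC than the average gene (53.8% against 50.4%). After GC correction 22 fell and 0 rose, with a median of -0.48 (camera adjusted p = 2.99e-05; 0.14 with an estimated correlation). The GC-corrected values were -0.57 for PKM, -0.47 for ENO1 and -0.29 for ALDOA.

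Cholesterol synthesis genes fell as well. Of 21 measured, 16 fell and 3 rose, the same as adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.011; 0.37 with an estimated correlation). DHCR7, a reductase of the last steps, fell from 181 ± 3.11 to 69.4 ± 1.98 CPM (log2 -1.38; GC-corrected -0.95). SREBF2, the transcription factor that controls the pathway, fell by 1.19 and the lanosterol synthase gene LSS fell by 1.05 (GC-corrected -0.76 and -0.62). The mean GC content of the list was 49.2%. After GC correction 20 of the 21 fell and 0 rose, with a median of -0.57 (camera adjusted p = 6.18e-06; 0.14 with an estimated correlation).

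All 13 mitochondrially encoded transcripts fell, also when adjusted over the list alone, with a median of -0.90 (camera adjusted p = 4.07e-05; 0.29 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, went from 23335 ± 486 to 12244 ± 108 CPM (log2 -0.93), and the complex I genes MT-ND1, MT-ND2 and MT-ND5 fell by 0.94, by 0.84 and by 1.72. The GC-corrected values were -1.19 for MT-CO1, -1.08 for MT-ND1, -1.41 for MT-ND2 and -2.10 for MT-ND5. These transcripts took 8.47% ± 0.09 of all counts in si-NC and 5.67% ± 0.03 in si-FOXM1 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). Their mean GC content was 44.2%, below the average gene, and after GC correction the median was -1.22 with all 13 lower (camera adjusted p = 2.37e-07; 0.14 with an estimated correlation).

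Of the 32 cytosolic ribosomal protein genes, 21 fell and 4 rose, the same as adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.014; 0.97 with an estimated correlation). RPL8, RPS2 and RPL13 fell by 0.73, by 0.74 and by 0.60 (GC-corrected -0.23, -0.29 and -0.23). After GC correction 22 fell and 5 rose (camera adjusted p = 0.039; 0.75 with an estimated correlation), and with limma on log2 FPKM the list was not called (adjusted p = 0.0514 at a pseudocount of 0.1 and 0.0515 at 1; over all settings from 0.000689 to 0.0515). Ribosomal protein genes have many processed pseudogenes, so reads can be shared with these copies. Of 19 immediate early genes, 14 fell and 3 rose, the same as adjusted over the list alone (camera adjusted p = 0.021; 0.29 with an estimated correlation). JUND fell by 1.10, EGR1 fell by 1.09, JUNB fell by 0.73 and SPRY2, a feedback inhibitor of growth factor signalling, fell by 0.72. The GC-corrected values were -0.64 for JUND, -0.75 for EGR1, -0.23 for JUNB and -0.81 for SPRY2. The mean GC content of this list was 55.1%, and after GC correction 12 fell, 3 rose and the list was no longer called (camera adjusted p = 0.23).

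**Figure D3:**
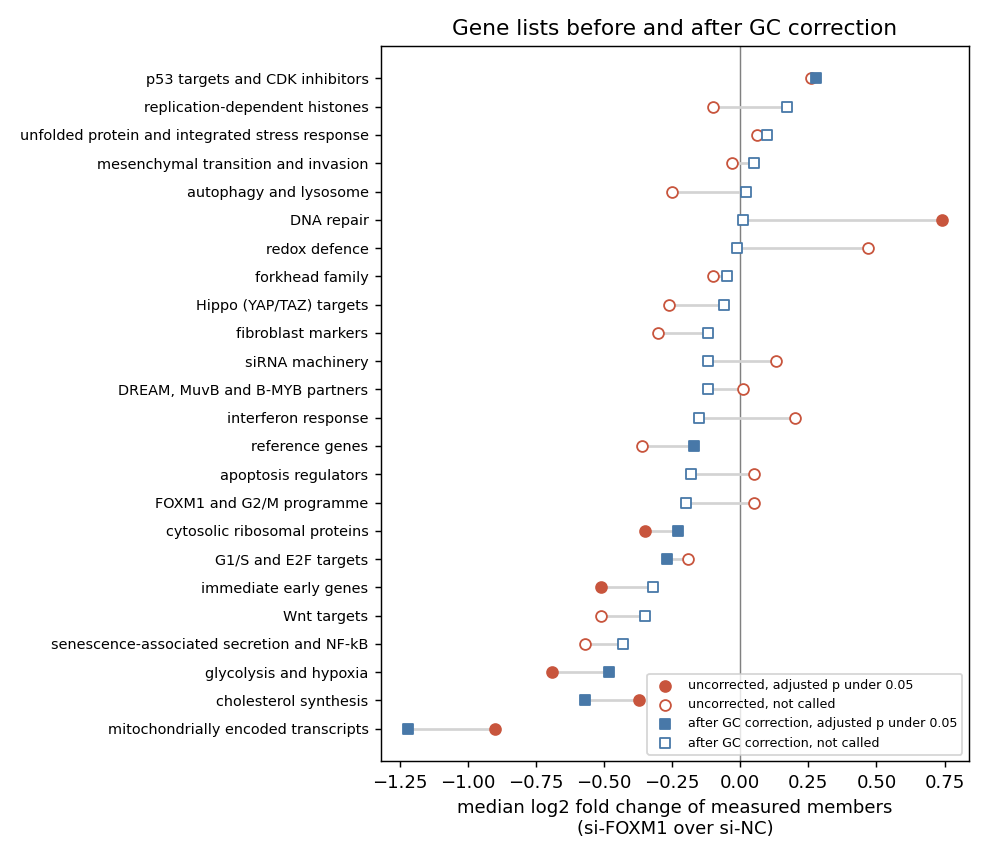
Median log2 fold change (si-FOXM1 over si-NC) of the measured members of the 24 gene lists tested; circles are uncorrected, squares GC-corrected, and filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. Of these, 6 were called before correction, 7 after and 4 in both; mitochondrially encoded transcripts lie lowest at -0.90 and -1.22.

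In total 6 of the 24 lists were called at the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. After GC correction 7 were called and again 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. The fry test called 15 lists, 11 lower and 4 higher. Median, mean and test did not share a sign for several lists. Apoptosis regulators and interferon response had medians and means above 0 and a camera direction of down, while the mesenchymal list (median -0.03, mean 0.19) and the fibroblast list (median -0.30, mean 0.08) had a camera direction of down and a fry direction of up.

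The other lists tested were not called by camera in the edgeR fit with TMM before correction, and their members went both ways. Of these, fry called redox defence and fibroblast markers higher and interferon response, Wnt targets, autophagy and lysosome, the forkhead list and reference genes lower. With the DESeq2 Wald test camera called redox defence higher (adjusted p = 0.0495) and reference genes lower (0.0457). Interferon response genes rose for 9 and fell for 8 of 18 (camera adjusted p = 0.92), with IFIT1 higher (log2 1.13; GC-corrected 0.39) and IRF1 and IFITM3 lower by log2 -1.35 and -0.72 (GC-corrected -1.11 and -0.32). After GC correction 3 interferon genes were higher, 6 lower and 9 not called (camera adjusted p = 0.61). Of 9 measured genes of senescence-associated secretion and NF-kB, 2 rose and 5 fell (camera adjusted p = 0.86). NFKBIA, RELB and TNF fell by 0.73, by 0.72 and by 1.36 (GC-corrected -0.50, -0.23 and -1.07), and GC correction left 2 of this list higher and 6 lower (camera adjusted p = 0.67). TNF was at a low level, with means of 2.16 CPM in si-NC and 0.84 CPM in si-FOXM1. In the unfolded protein and integrated stress response 9 rose and 7 fell of 22 (camera adjusted p = 0.92), with the endoplasmic reticulum chaperone gene HSP90B1 at log2 1.48 (GC-corrected 0.86); after correction 9 were higher and 6 lower (camera adjusted p = 0.51). Redox defence genes rose for 12 and fell for 4 of 17 (camera adjusted p = 0.089), with SOD2 at log2 1.07 and HMOX1 at 0.84 (GC-corrected 0.39 and 1.26), but GC correction left 7 higher and 7 lower (camera adjusted p = 0.61). Among mesenchymal and invasion genes 8 rose and 8 fell of 18 (camera adjusted p = 0.92); the transcription factor gene ZEB1 rose from 6.47 ± 0.95 to 30.6 ± 3.82 CPM (log2 2.23; GC-corrected 1.34), and the integrin gene ITGB1 rose before correction (log2 0.90) but not after (-0.04). Corrected for GC, 7 mesenchymal genes were higher and 6 lower (camera adjusted p = 0.61). Apoptosis regulators rose for 8 and fell for 8 of 16 (camera adjusted p = 0.92), with BIRC2 at log2 1.34 (GC-corrected 0.38); the corrected counts were 5 higher and 9 lower (camera adjusted p = 0.61). For each of these 6 lists the counts before and after correction adjusted over the list alone were the same.

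Wnt targets rose for 2 and fell for 8 of 11 (camera adjusted p = 0.30), with MYC at log2 -0.51 and the ubiquitin ligase gene ZNRF3 at -0.80 (GC-corrected -0.24 and -0.55); after correction 2 were higher and 4 lower (camera adjusted p = 0.56). Hippo (YAP/TAZ) targets rose for 5 and fell for 9 of 18 (camera adjusted p = 0.59), with AXL at -0.67 (GC-corrected -0.39), and for 5 and 5 after correction (camera adjusted p = 0.90). Of 22 autophagy and lysosome genes 9 rose and 11 fell (camera adjusted p = 0.43), with CTSD at -0.67 (GC-corrected -0.18); after correction 6 were higher and 10 lower (camera adjusted p = 0.98). The forkhead list as fixed held 13 measured genes other than FOXM1, of which 4 rose and 5 fell (camera adjusted p = 0.86; after GC correction 2 higher and 4 lower, 0.98). It included FOXRED1 (log2 -0.47, GC-corrected -0.08), an oxidoreductase gene that is not a forkhead gene. Without it 4 of 12 rose and 4 fell, the same as adjusted over the list alone (camera adjusted p = 0.92; after GC correction 2 higher and 4 lower). FOXN2 stood at log2 1.12 before and -0.05 after GC correction, and FOXK2 at -0.50 and -0.15. Among 9 replication-dependent histone genes 1 rose and 3 fell (camera adjusted p = 0.92; after GC correction 2 higher and 1 lower, 0.61), and these share sequence with near-identical copies. In the siRNA machinery 5 rose and 5 fell of 12 (camera adjusted p = 0.92), with the Argonaute gene AGO2 at -0.88 (GC-corrected -1.11) and TARBP2 at -0.79 (GC-corrected -0.32); after correction 3 were higher and 6 lower (camera adjusted p = 0.61). The 14 reference genes split into 5 higher and 9 lower (camera adjusted p = 0.30), with GAPDH at log2 -0.55 and ACTB at -0.45. After GC correction these were -0.10 and -0.09, while 10 reference genes fell and 0 rose (camera adjusted p = 0.038; 0.75 with an estimated correlation). For each of these 7 lists the counts before and after correction adjusted over the list alone were the same.

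Markers of other cell types were measured to different extents. Of 10 fibroblast markers 9 were measured, of which 3 rose and 4 fell, the same as adjusted over the list alone (camera adjusted p = 0.86), and after GC correction 4 were higher and 3 lower (0.90). LUM rose from 60.1 ± 1.79 to 233 ± 6.61 CPM (log2 1.95; GC-corrected 0.88), COL3A1 fell by 0.42 (GC-corrected -0.25), and DCN stood at log2 0.27 before and -0.69 after GC correction. Among blood cell markers 1 of 10 was measured, CD68 (log2 -0.13, edgeR adjusted p = 0.63; GC-corrected 0.21), and 0 of 8 endothelial markers. Of the keratins 3 were measured, of which KRT8 and KRT18 fell by 0.74 and by 0.36, also when adjusted over the list alone; KRT8 stood at -0.27 and KRT18 at 0.11 after GC correction. Of 14 ovarian and Mullerian epithelial markers 2 were measured, with FOLR1 at log2 -0.63 and NAPSA at 1.31 (GC-corrected -0.30 and 1.74), and the call of FOLR1 was lost after GC correction, with library size alone (adjusted p = 0.0633) and with limma on FPKM at a pseudocount of 0.1 (0.0524) or 1 (0.0522). NAPSA was at a low level, with means of 0.59 CPM in si-NC and 1.48 CPM in si-FOXM1.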

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

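Of these settings, the GC corrections, limma on log2(FPKM + 1), the forkhead list without FOXRED1 (6 lists called) and the fits without AGATAT genes were chosen after the data were seen. FOXM1 stayed lower and called in every setting run for it, between -3.77 and -3.64 on the log2 scale when 1 library was left out. Leaving out 1 library gave 9277 to 9547 genes (4695 to 4844 higher, 4578 to 4703 lower), 5 to 6 called lists and 21 of 21 calls among FOXM1 and the 20 largest changes. A minimum of 2-fold reduced the genes to 2164, since it only removes calls. The calls lower in si-FOXM1 numbered 3078 with limma at a pseudocount of 0.1 and 3092 at a pseudocount of 1, on FPKM without TMM scaling, against 4762; the cause was not tested. The DESeq2 Wald test, with its statistic in camera, called 10 lists in place of 6, adding G1/S, p53, redox and reference genes; the cause was not tested. Omitting the filter changed nothing, as the filter removed 0 genes, and the stricter filter, DESeq2 size factors and the authors' adjusted p moved no count by over 1.5 times. Same-numbered libraries of the groups had deviations that correlated at -0.016, 0.01 and -0.095 across genes, so the numbers were not taken as pairs, and not every library correlated best with its own number. The replicate block gave 9571 genes, and with GC correction 7484, of which 3216 were higher. Of 118 named genes besides FOXM1, 12 changed in call, or in direction with a call on either side, under any setting and 5 under one chosen before. KRT10 and CD68, called in no setting, also changed sign, under settings of both kinds. Among those called before it, GC correction turned the sign of ITGB1 (-0.035), KRT18 (0.11), FOXN2 (-0.051), HIST1H2BK (0.22), HIST1H1C (0.17), AGO3 (-0.058) and DCN (-0.69), and ended 4 further calls. After correction KRT18, HIST1H2BK and DCN were called in the new direction, while ITGB1, FOXN2, HIST1H1C and AGO3 were not called. For HIST1H1C library size alone also turned the sign (0.016). The cause was not tested beyond the GC trend that the correction removes. DNA repair turned to a direction of down without AGATAT genes after GC correction (adjusted p = 0.73). In counts simulated for 3 libraries per group without a GC trend, 41 of 50 genes changed 1.5-fold were recovered. With a linear GC trend added, 27 of 50 were recovered without the correction and 36 of 50 with it.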

Other observations

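The genes and groups of this paragraph and the next were chosen after their values were seen. Zinc finger genes with a ZNF symbol moved mostly one way: of 391 measured, 271 rose and 68 fell, with a median log2 fold change of 0.92. Their mean GC content was 47%, against 50.4% for all genes. After GC correction 227 rose and 34 fell, with a median of 0.47 against -0.07 for all other genes. Members of this family share sequence, so reads can be split between relatives. The authors' deposited gene ontology terms gave 2 calls among 980 terms of 15 to 300 genes, canonical glycolysis (2 higher, 18 lower, camera adjusted p = 0.0052) and gluconeogenesis (2 higher, 22 lower, 0.0052). After GC correction camera called 0 terms, with 90 at an unadjusted p under 0.05, led by canonical glycolysis (17 lower, 1 higher, adjusted p = 0.066), ribosome biogenesis (15 higher, 2 lower, 0.066) and long-chain fatty-acyl-CoA synthesis (19 lower, 1 higher, 0.066).

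Ranked by the GC-corrected value, large falls not described above included KIAA0101, which encodes a PCNA-associated factor (47.5 to 16 CPM, log2 -2.36 corrected), SGPP1, a sphingosine-1-phosphate phosphatase (16 to 6.49 CPM, -2.09), TMEM64 (27.1 to 11.3 CPM, -2.07) and the kinase gene UHMK1 (129 to 62.9 CPM, -2.04). Large rises included TPM4, a tropomyosin, from 107 to 536 CPM (2.15 corrected), SHISA9 from 8.32 to 45.3 CPM (2.34) and OGFR from 29.5 to 81.7 CPM (1.96). These levels are means of 3 libraries, and exons of KIAA0101, TMEM64, TPM4 and SHISA9 overlap those of other genes. Of the 14 largest corrected falls besides FOXM1, 11 could be searched for AGATAT in the 3' UTR and 8 held it. Of the 15 largest rises, 14 could be searched and 2 held it. These counts are not adjusted for 3' UTR length, on which the chance of holding a word depends. That length ran from 351 to 8515 bases among the falls searched and from 124 to 5004 among the rises.

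Among the tests below, those of the slope within lists, the slopes per library, the mitochondrial transcripts and the words made of the same bases were chosen only after the result was seen, as were the GC correction and the word scan. The test of same-base words was changed after its result was seen. Its first form took the strongest other word of the same bases, fitted alone, and asked whether it reached 0.5 of the effect. By that form GATATA reached 0.6 and CGGAGAT 0.697, so it would not have argued against base composition. Both words overlap the site itself, and the joint fit given below replaced that form for this reason. For TCGGAGA the first form had been set before its result was seen. Only 1 of the 10 splits of the 6 libraries, the real one, called as many genes: 9684 against at most 0 in the others by edgeR (at most 30 at an unadjusted p under 0.05), and 7726 against at most 0 after GC correction (at most 84 unadjusted). For lists it was 1 of 10, with 6 called against at most 5. With 10 splits no share under 0.05 can be reached.

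The first pattern is the trend of fold change with GC content. Transcript length alone is argued against, since the weakest Spearman's rho of fold change with GC over 10 equal groups by length was -0.578. A GC-dependent read yield that differed between the groups is a candidate explanation: the median slope within 21 lists of related genes was -0.588 log2 per 10 GC points, against -0.571 over all genes, and 20 of 21 were negative. A response of the cells that follows base composition cannot be told apart from it, because the slopes of 0.261 to 0.307 in si-NC and -0.27 to -0.296 in si-FOXM1 (mean difference -0.571) go with the groups, and no batch is labelled. The fall of the mitochondrially encoded transcripts is not accounted for by such a yield, as their median moved to -1.22 (SD 0.43, 13 transcripts) after correction.

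The second pattern is that genes with AGATAT in the 3' UTR were lower, relative to other genes after the regression. AGATAT was the strongest of 4096 words of 6 bases (2690 genes, effect -0.11 log2, SE 0.012, t = -9.84, against at most 4.99 in 100 permutations), and CAGATATA had -0.255 (SE 0.0282, 231 genes) in the same scan. AGATAT was in 65.6% of 247 genes called at least 2-fold lower after GC correction against 26.4% of others. These shares, unlike the scan, are not adjusted for 3' UTR length. GC content and base-pair composition had been regressed out before the scan, which by itself brings the effects of same-base words near 0. The test of these words therefore cannot decide whether base composition is a cause. It shows only that other words of the same bases did not share the effect of AGATAT in a joint fit after the regression. The other 59 words of the same bases, each fitted with AGATAT, had a median effect of 0.00361. Of them 0 reached 0.5 of its effect (largest GATATA, -0.0413). Pairing of the FOXM1 siRNA's seed with these 3' UTRs may be a cause, since the coding-sequence effect was 0.35 (SE 0.1) of that in the 3' UTR. The prediction as written asked only for a ratio under 0.5. In reading it, a margin of more than the SE was also asked for, and a wider margin could leave this undecided. AGATAT, within CAGATATA, lies in the coding sequence of FOXM1, but the FOXM1 mRNA holds 48.9% of the tested words of 6 bases and 6% of those of 8, and without the siRNA sequence, not given in the sources used here, whether a seed matches stays open.

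The third pattern is that genes with TCGGAGA in the 3' UTR were higher in si-FOXM1, relative to other genes after the regression (172 genes, effect 0.22 log2, SE 0.032, t = 6.86, against at most 5 in 100 permutations). In a separate fit by site class the effect was 0.31 (SE 0.062) for the 46 genes with TCGGAGAA and 0.0479 (SE 0.0209) for the 442 with only CGGAGA. The median GC-corrected log2 fold change was 0.228 for those 46 but -0.0184 for the other 126 with TCGGAGA. It was -0.0877 with only CGGAGA and -0.0836 without CGGAGA. TCGGAGA was in 2.94% of 477 genes called at least 2-fold higher after GC correction, against 1.67% of others. It was in 2.43% of 247 called 2-fold lower, against 1.71%. These shares are not adjusted for 3' UTR length. As for AGATAT, the test of same-base words cannot decide whether base composition is a cause, because of the regression before it. The other 419 words of the same bases had a median effect of 0.00323. Each was fitted with TCGGAGA, and 2 reached 0.5 of its effect. Words with GGAGAA or AGGAGA and without TCGGAGA also went with higher genes, over more genes and with smaller effects. Among them were GGAGAAA (t = 6.54, 1912 genes), GGAGAA (t = 5.92, 3944 genes) and AGGAGAA (t = 5.53, 2083 genes). The 3 words of 8 bases with the largest t do not hold TCGGAGA, but they lie in 805 to 1071 genes with effects of 0.0786 to 0.0893. Rank by t thus also follows the number of genes. These words were not fitted together with TCGGAGA, so whether the pattern is specific to it stays open. TCGGAGA also lies in the coding sequence of FOXM1, whose mRNA holds 17.9% of the tested words of 7 bases. A seed of the si-NC siRNA that lowered genes with TCGGAGA in the control libraries cannot be told apart from other causes here. The coding-sequence effect was 0.44 (SE 0.1) of that in the 3' UTR, which met the prediction as written, a ratio under 0.5. That ratio lay within its SE of 0.5, too near to decide, and no si-NC sequence was given in the sources used here.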
